A study of Gallus gallus with 24 samples.

How the data were processed

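The deposited table gives 1 signal value per gene and library, a normalized read count that the authors obtained by dividing counts by 1 size factor per library. It has 24356 gene rows and 24 library columns, and 21118 genes have a value above 0 in at least 1 library. A gene symbol is given in 13605 rows and the other rows carry only an identifier. Dividing each column by its smallest step returned whole reads for 100% of the values within 0.001 of a read. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.5b, StringTie 2.1.4, DESeq2 1.34.0 and the genome build GRCg6a were used. With StringTie among the tools, the whole reads may themselves be estimates. The counter settings and the strand setting are not given in the sources used here. Libraries were made per the labels from 100 ng of total RNA with a directional poly(A) kit and 13 PCR cycles, each from 1 biological replicate of 3 pooled explants at embryonic day 4. Reads of genes that overlap, lie antisense to each other or have close paralogs remain uncertain in such a table, and no genome coordinates were used.

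The plan of comparisons, gene lists, alternatives and named genes was made before the data were examined. Values were transformed to log2 of the normalized count plus 1, and the 15001 genes with a mean of at least 10 over the 24 libraries were tested, 11469 of them with a symbol. Fold changes on this scale are smaller than ratios of counts for genes with low values. One limma model (limma-trend) with 8 group means and 16 residual degrees of freedom gave all 15 comparisons, with Benjamini-Hochberg adjustment within a comparison and genes called under an adjusted p of 0.05. An interaction was the DCA effect with FGF2 minus that without, and effects were compared between times as 48 h minus 24 h. The ± after a log2 fold change is the SE of that model, which pools the variance of all groups. The 25 gene lists were fixed from general knowledge with 612 genes, of which 548 were in the table and 538 were tested. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists of a comparison. A second p used the correlation estimated between its genes (estimated r), and counts over the list alone adjust gene p values over its members. Lists of markers for mesenchyme, blood, endothelium, lens and surface ectoderm, and neural crest with melanocytes and muscle stood for other cells that explants can hold.

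Named genes in the Results follow 3 rules. They are the 6 highest and 6 lowest fold changes with a symbol, separate replicates and a mean of at least 100, up to 4 members with the smallest adjusted p of a list that the text describes, and a fixed set of 20 eye, FGF, metabolic and growth genes. MKI67 and TRIB3 of that set have no row in the table. Only some of the genes that meet the rules are named.

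In a self-test on simulated counts, drawn independently for each gene, changes were planted in the simulated FGF2 group at 24 h. Against the simulated control at 24 h, the model recovered 43.28% of 1.5-fold, 65.67% of 2-fold and 83.33% of 4-fold changes. Of 133 genes called there, 4 were not planted, a false share of 3.01%. In the 10 comparisons between simulated groups without planted changes no gene was called. Of 500 random lists in simulated DCA against control at 48 h, 4% had a camera p under 0.05, which leaves correlated genes untested.

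Results were repeated with other pseudocounts, filters, scalings, fits, a replicate block, a 2-fold threshold, edgeR and DESeq2 on the recovered reads, and with each library left out. The tools used here were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.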

Results

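Polyadenylated RNA was sequenced from explants of retinal pigment epithelium (RPE), the pigmented cell layer that backs the retina, taken from chicken embryos at embryonic day 4. In the embryonic chick, RPE exposed to fibroblast growth factor 2 (FGF2) can lose its pigment and form neural retina. Explants received plain maintenance medium (control), FGF2 at 10 ng/ml, dichloroacetate (DCA) at 20 mM, or both together, for 24 or 48 h. DCA inhibits the pyruvate dehydrogenase kinases and thereby favours entry of pyruvate into mitochondrial oxidation. The design asks what FGF2 does to RPE gene expression, what DCA does on its own, and whether DCA alters the response to FGF2. Each of the 8 groups had 3 biological replicates of 3 pooled explants, which gave 24 libraries. Levels are given as mean ± SD of normalized read counts (n = 3), and changes as log2 fold change ± SE with the adjusted p of limma.

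The depth recovered from the deposited table ran from 32.82 to 72.72 per library in units of 1e6 reads, with a median of 37.455. The third replicates of the FGF2 groups were the deepest, at 69.01 (24 h) and 72.72 (48 h) of these units, and the other 22 libraries held 32.82 to 47.07. Between 15855 and 17429 genes had a value above 0 in a library, and mitochondrially encoded genes took 6.163% to 8.014% of the total. Replicates of a group correlated at Pearson r of 0.9588 to 0.9804 across genes. The first 3 principal components of the log2 values held 25.1%, 18.5% and 12.8% of the variance. Of 15001 genes tested, between 438 and 8187 passed in each of the 15 comparisons.

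**Figure D1:**
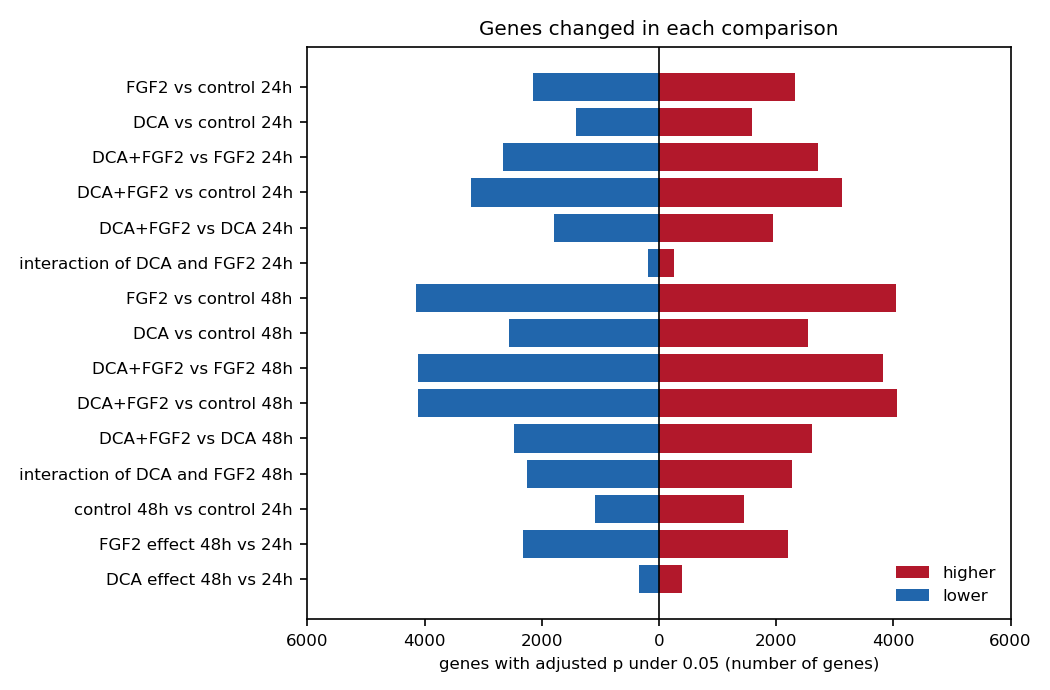
Genes with higher values (bars to the right) and lower values (bars to the left) in each of the 15 comparisons, of 15001 tested, at a limma adjusted p under 0.05. FGF2 against control at 48 h had the most, 4036 higher and 4151 lower, and the interaction at 24 h the fewest, 252 and 186.

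After 24 h of FGF2, retinal progenitor genes stood above control, led by the eye-field homeobox factor SIX6 (ENSGALG00000020359, 3.42 ± 0.13, adjusted p = 6.5e-14), whose level went from 2225 ± 42.3 to 23886 ± 1061 normalized counts. The neural stem cell factor SOX2 (ENSGALG00000043460, 2.95 ± 0.26, adjusted p = 1.5e-08) and the retinal homeobox factor LHX2 (ENSGALG00000001124, 1.23 ± 0.10) also rose, as did PAX6 (ENSGALG00000012123, 1.09 ± 0.16), the regulator of eye development (adjusted p = 1.8e-05 or less). Of 24 progenitor genes tested, 15 rose and 3 fell. The median was 0.79, with 15 higher and 3 lower over the list alone, and a camera adjusted p = 2.9e-05 (0.059 with estimated r). Retinal neuron genes followed with 14 of 25 higher and 3 lower. Their median was 1.22 (camera adjusted p = 0.0034, 0.18 with estimated r), with 14 higher and 4 lower over the list alone. They included the amacrine and horizontal cell factor FOXN4 (ENSGALG00000005062, 3.88 ± 0.31, adjusted p = 5e-09), the microtubule proteins DCX (ENSGALG00000007993, 2.53 ± 0.22) and STMN2 (ENSGALG00000039690, from 0 ± 0 to 236 ± 104) in normalized counts, and ATOH7 (ENSGALG00000052760, 1.06 ± 0.29, adjusted p = 0.0079), which is needed for retinal ganglion cells. Pigment and RPE genes were split, 10 of 26 lower and 3 higher. A median of -0.42 went with a camera adjusted p = 0.0025 (0.31 with estimated r), with 3 higher and 12 lower over the list alone. Among them the amino acid transporter SLC6A15 (ENSGALG00000010992, -2.65 ± 0.17), the RPE factor OTX2 (ENSGALG00000034889, -1.16 ± 0.08), the melanosome protein MLANA (ENSGALG00000019756, -2.63 ± 0.32) and the melanin enzyme TYR (ENSGALG00000017237, -0.78 ± 0.24) fell (adjusted p = 0.015 or less, and 0.079 for TYR without the first FGF2 replicate). PMEL (ENSGALG00000035350), the melanosome fibril protein, was at 78769 ± 8825 in control and 79186 ± 12647 with FGF2, a log2 fold change of 0.00 ± 0.18 (adjusted p = 1).

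Targets of FGF signalling through ERK rose after 24 h of FGF2, 12 of 19 genes against 1 that fell. The median was 0.49, with 12 higher and 1 lower over the list alone, and a camera adjusted p = 2.3e-06 (0.029 with estimated r). The ERK phosphatases DUSP4 (ENSGALG00000011419, 2.00 ± 0.12) and DUSP6 (ENSGALG00000011207, 1.88 ± 0.14), the feedback inhibitor SPRY1 (ENSGALG00000042067, 1.62 ± 0.14) and the ETS factors ETV4 (ENSGALG00000036678, 1.74 ± 0.11) and ETV5 (ENSGALG00000005768, 0.45 ± 0.12) were all higher (adjusted p = 0.0047 or less). Cell cycle genes moved together, with 36 of 38 higher and 0 lower. Their median was 0.93 (camera adjusted p = 6.8e-18, 0.16 with estimated r), with 38 higher and 0 lower over the list alone. Cyclin A2, CCNA2 (ENSGALG00000011881, 0.85 ± 0.10), and the ribonucleotide reductase subunit RRM1 (ENSGALG00000017350, 0.91 ± 0.11) were examples (adjusted p = 1.7e-06 or less). All but 1 of the 20 sterol biosynthesis genes rose and 0 fell, among them the pathway's transcription factor SREBF2 (ENSGALG00000041687, 0.67 ± 0.06). A median of 0.73 went with a camera adjusted p = 3.4e-11 (0.13 with estimated r), with 19 higher and 0 lower over the list alone. Glycolysis and lactate genes rose in 12 of 21 cases and fell in 1. The median was 0.37, with 12 higher and 1 lower over the list alone, and a camera adjusted p = 7.5e-06 (0.045 with estimated r). LDHB (ENSGALG00000035836, 1.08 ± 0.08, adjusted p = 9e-10), LDHA (ENSGALG00000006300, 1.09 ± 0.12, adjusted p = 4.3e-07) and enolase ENO1 (ENSGALG00000002377, 0.85 ± 0.08) were higher, while the glucose transporter SLC2A1 (ENSGALG00000004889) had a log2 fold change of 0.16 ± 0.12 (adjusted p = 0.36). In the same libraries matrix genes were lower, 15 of 28 against 2 higher, as with the collagen cross-linking enzyme LOX (ENSGALG00000028063, -2.24 ± 0.16, adjusted p = 8.2e-10) and smooth muscle actin ACTA2 (ENSGALG00000006343, -2.25 ± 0.16). Their median was -0.40 (camera adjusted p = 2.3e-05, 0.045 with estimated r), with 2 higher and 16 lower over the list alone. Markers of other cells went down beside all of these groups. Of 16 periocular mesenchyme markers 12 fell and 1 rose, of 14 blood markers 11 fell and 0 rose, and of 10 endothelial markers 7 fell and 0 rose. For the mesenchyme markers the median was -0.97, with 1 higher and 12 lower over the list alone, and a camera adjusted p = 2.3e-05 (0.13 with estimated r). For the blood markers the median was -0.73, with 0 higher and 13 lower over the list alone, and a camera adjusted p = 2.9e-05 (0.16 with estimated r). For the endothelial markers the median was -0.79, with 0 higher and 8 lower over the list alone, and a camera adjusted p = 0.00034 (0.28 with estimated r). The matrix and mesenchyme lists share 6 genes. Outside the lists, large rises were in the nitric oxide synthase NOS1 (ENSGALG00000008177, from 2.44 ± 4.23 to 825 ± 76.1) and the forebrain factor FEZF2 (ENSGALG00000007184, from 0 ± 0 to 152 ± 91.7), and large falls in the transcription factor DMRT3 (ENSGALG00000010161, from 138 ± 11.6 to 1.55 ± 2.69) and the phototransduction regulator GUCA1A (ENSGALG00000001431, from 276 ± 93.8 to 4.31 ± 4.76), all in normalized counts (adjusted p = 5.5e-06 or less). In all, 4466 genes passed, 2322 higher and 2144 lower, and 1483 of them changed at least 2-fold.

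At 48 h the FGF2 explants differed from control in 8187 genes, 4036 higher and 4151 lower, of which 3015 changed at least 2-fold. Pigment genes were now lower as a group, 23 of 26 against 1 higher. A median of -1.76 went with a camera adjusted p = 6.8e-09 (0.069 with estimated r), with 1 higher and 23 lower over the list alone. PMEL went from 75584 ± 5080 to 18091 ± 3244 normalized counts (-2.08 ± 0.18, adjusted p = 2.4e-09), tyrosinase from 27337 ± 1770 to 4000 ± 547 (-2.78 ± 0.24, adjusted p = 2.3e-09), and OCA2 (ENSGALG00000016740, -1.70 ± 0.11), SLC6A15 (-2.77 ± 0.17), OTX2 (-1.17 ± 0.08) and MITF (ENSGALG00000039583, -0.61 ± 0.12), the main regulator of pigment genes, also fell (adjusted p = 0.0002 or less). Progenitor genes rose in 23 of 24 cases and fell in 1. The median was 1.80, with 23 higher and 1 lower over the list alone, and a camera adjusted p = 1.6e-11 (0.0066 with estimated r). SOX2 climbed from 62.6 ± 9.93 to 2982 ± 204 (5.56 ± 0.26, adjusted p = 3.2e-13) and SIX6 from 3866 ± 209 to 28675 ± 1516 (2.89 ± 0.13, adjusted p = 1.9e-13). The retinal factors RAX2 (ENSGALG00000013431, 2.97 ± 0.16), SIX3 (ENSGALG00000032259, 2.14 ± 0.12) and PAX6 (1.94 ± 0.16) were higher too (adjusted p = 1.4e-09 or less). Retinal neuron genes rose in 17 of 25 cases and fell in 1. Their median was 2.03 (camera adjusted p = 1.3e-05, 0.069 with estimated r), with 17 higher and 1 lower over the list alone. ATOH7 went from 88.5 ± 28.1 to 3156 ± 336 (5.19 ± 0.29, adjusted p = 4.7e-12), with FOXN4 (8.06 ± 0.31), DCX (4.97 ± 0.22) and the Notch ligand DLL1 (ENSGALG00000011182, 3.51 ± 0.18) alongside (adjusted p = 1.3e-12 or less).

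All 38 cell cycle genes tested rose at 48 h of FGF2 and 0 fell. A median of 2.00 went with a camera adjusted p = 5.5e-22 (0.1 with estimated r), with 38 higher and 0 lower over the list alone. They included E2F1 (ENSGALG00000003045, 3.01 ± 0.12, adjusted p = 4.4e-14), the S-phase transcription factor, the replication helicase subunit MCM2 (ENSGALG00000006037, 2.00 ± 0.12) and cyclin D1, CCND1 (ENSGALG00000007555, 1.71 ± 0.11). Likewise 20 of 20 sterol genes rose and 0 fell, with squalene epoxidase SQLE (ENSGALG00000036915, 2.42 ± 0.13, adjusted p = 1.9e-12) as an example. The median was 1.73, with 20 higher and 0 lower over the list alone, and a camera adjusted p = 2.4e-14 (0.069 with estimated r). In glycolysis 14 of 21 genes rose and 1 fell, with ENO1 (1.91 ± 0.08, adjusted p = 5.3e-14), LDHA (1.17 ± 0.12, adjusted p = 3.6e-08) and SLC2A1 (0.42 ± 0.12, adjusted p = 0.0058) higher. Their median was 0.45 (camera adjusted p = 2e-04, 0.069 with estimated r), with 14 higher and 1 lower over the list alone. ERK targets went both ways, 9 higher and 5 lower of 19, and the list as a whole did not pass (camera adjusted p = 0.15). DUSP6 (1.53 ± 0.14), SPRY2 (ENSGALG00000016906, 1.51 ± 0.13) and ETV5 (0.92 ± 0.12) were higher and the immediate-early factor EGR1 (ENSGALG00000007669, -1.22 ± 0.11) lower (adjusted p = 6.8e-07 or less). Matrix genes fell in 21 of 28 cases and rose in 2, among them the mesenchymal factor SNAI1 (ENSGALG00000008018, -2.95 ± 0.12, adjusted p = 5.3e-14), ACTA2 (-3.00 ± 0.16) and the proteoglycan decorin, DCN (ENSGALG00000011274, -3.10 ± 0.17). A median of -1.48 went with a camera adjusted p = 3.3e-08 (0.0078 with estimated r), with 2 higher and 21 lower over the list alone. Lysosomal genes were lower in 22 of 27 cases and higher in 2 (median -0.49, camera adjusted p = 1.2e-05, 0.1 with estimated r). Beside these groups, markers of other cells were lower: 15 of 16 for mesenchyme, 14 of 14 for blood and 10 of 10 for endothelium, and 0, 0 and 0 were higher. Their medians were -2.76, -1.49 and -2.27, with camera adjusted p = 1.3e-09, 4.2e-06 and 2.7e-06 (0.039, 0.1 and 0.13 with estimated r). Adjusted over the list alone, 15, 14 and 10 fell. The mesenchyme factor TCF21 (ENSGALG00000029024, from 146 ± 14 to 0 ± 0) in normalized counts, embryonic haemoglobin HBZ (ENSGALG00000023740, -2.16 ± 0.23), the macrophage receptor CSF1R (ENSGALG00000005725, -1.58 ± 0.18) and the endothelial proteins VWF (ENSGALG00000017272, -2.63 ± 0.22) and CDH5 (ENSGALG00000032349, -2.45 ± 0.22) were examples (adjusted p = 1.2e-07 or less). Of further markers chosen after this was seen, 23 of 31 for mesenchyme, 22 of 29 for macrophages and 14 of 16 for endothelium fell.

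**Figure D2:**
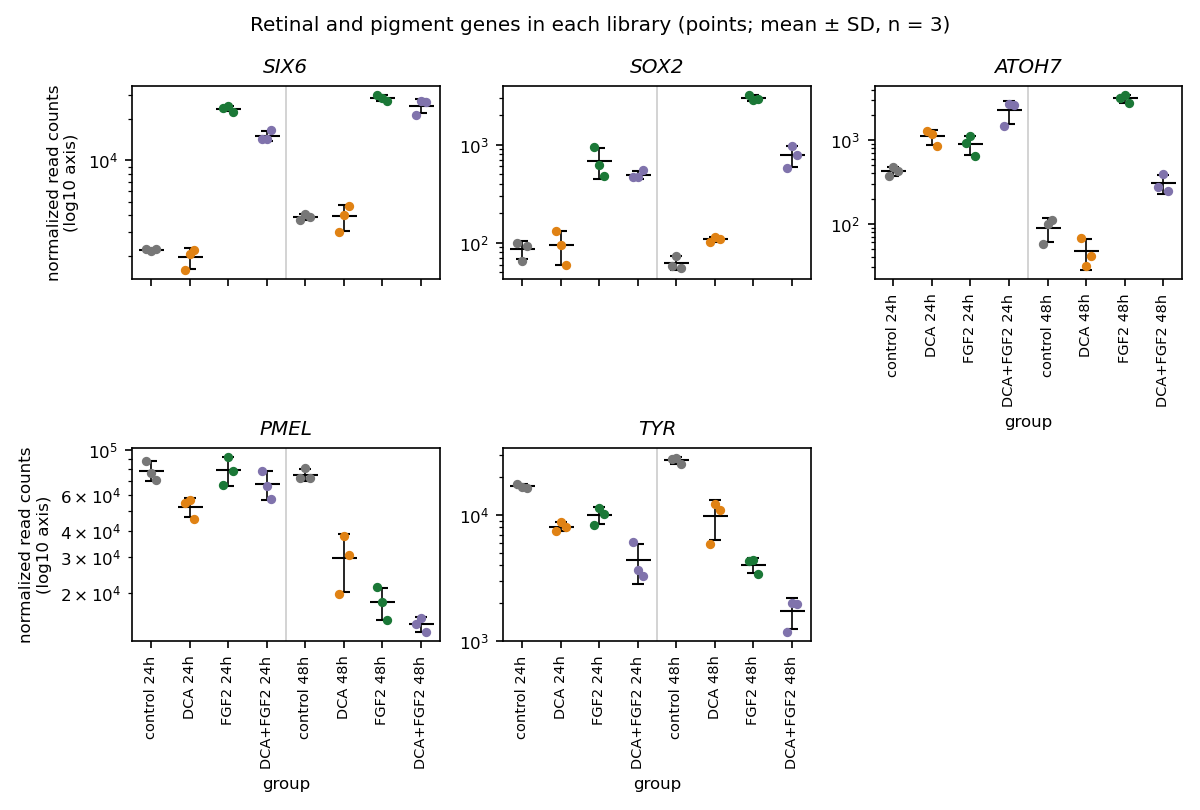
Normalized read counts (log10 axis) of 3 retinal genes (SIX6, SOX2, ATOH7) and 2 pigment genes (PMEL, TYR) in every library, with points for libraries and bars for group means ± SD, n = 3. At 48 h SOX2 averaged 62.6 ± 9.93 in control, 2982 ± 204 with FGF2 and 781 ± 193 with FGF2 and DCA.

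The FGF2 effect itself differed between 48 h and 24 h in 4524 genes, 2208 more positive and 2316 more negative at 48 h, 1492 of them by at least 2-fold. Progenitor and neuronal regulators gained, with a more positive effect on HES5 (ENSGALG00000001141, 4.94 ± 0.48, adjusted p = 2.3e-07), a Notch effector, ATOH7 (4.13 ± 0.41, adjusted p = 3.2e-07), SOX2 (2.61 ± 0.36) and DLL1 (2.85 ± 0.25). In the progenitor list 15 of 24 gained and 3 lost, and in the neuron list 11 and 2 of 25. For the progenitor genes the median was 0.87, with 16 positive and 3 negative over the list alone, and a camera adjusted p = 3e-08 (0.018 with estimated r). For the neuronal genes the median was 1.04, with 11 positive and 2 negative over the list alone, and a camera adjusted p = 4e-04 (0.11 with estimated r). For cell cycle genes the effect was more positive in 36 of 38, E2F1 (2.26 ± 0.16) and CCND1 (1.25 ± 0.16) among them. The median was 1.07, with 38 positive and 0 negative over the list alone, and a camera adjusted p = 7.9e-17 (0.15 with estimated r). Pigment genes lost in 17 of 26 cases and gained in 1, PMEL (-2.08 ± 0.25, adjusted p = 3.4e-06), TYR (-2.00 ± 0.33) and OCA2 (-1.46 ± 0.15) included. Their median was -1.42 (camera adjusted p = 2.9e-07, 0.11 with estimated r), with 1 positive and 17 negative over the list alone. Matrix genes had a more negative effect in 17 of 28 cases and a more positive one in 2, lysosomal genes in 18 of 27 and 0. For the matrix genes the median was -0.83, with 2 positive and 20 negative over the list alone, and a camera adjusted p = 2.4e-07 (0.018 with estimated r). For the lysosomal genes the median was -0.52, with 0 positive and 21 negative over the list alone, and a camera adjusted p = 1.7e-09 (0.048 with estimated r). Mesenchyme markers moved with them, 15 of 16 more negative and 0 more positive. A median of -1.60 went with a camera adjusted p = 1.6e-09 (0.039 with estimated r), with 0 positive and 15 negative over the list alone. So did endothelial markers, 8 of 10 more negative and 0 more positive (median -1.15, camera adjusted p = 9.4e-05, 0.2 with estimated r), and blood markers, 5 and 0 of 14 (median -0.55, camera adjusted p = 0.0044, 0.29 with estimated r). The effect on MITF was also more negative at 48 h (-0.94 ± 0.17, adjusted p = 0.00027). In the planned test, 8 of 100 splits of the libraries gave at least 4524 genes.

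DCA alone for 24 h raised redox and stress genes. Thioredoxin reductase TXNRD1 (ENSGALG00000035345, 1.81 ± 0.12, adjusted p = 1.1e-08) went from 762 ± 65.1 to 2682 ± 261 normalized counts, and sulfiredoxin SRXN1 (ENSGALG00000054306, 0.90 ± 0.11) and the autophagy receptor SQSTM1 (ENSGALG00000035804, 0.62 ± 0.07) rose with it (adjusted p = 1.1e-05 or less). Of 20 NRF2 and oxidative stress genes 7 rose and 2 fell. The median was 0.20, with 10 higher and 2 lower over the list alone, and a camera adjusted p = 0.0038 (0.36 with estimated r). The p53 list had 9 of 17 higher and 0 lower, with the cell cycle inhibitor p21, CDKN1A (ENSGALG00000028318, 1.36 ± 0.12, adjusted p = 2.8e-07), and CCNG1 (ENSGALG00000001718, 0.83 ± 0.06), a p53 target. Their median was 0.36 (camera adjusted p = 5.7e-05, 0.029 with estimated r), with 9 higher and 0 lower over the list alone. Integrated stress response genes rose in 14 of 30 cases and fell in 4, among them the response's main factor ATF4 (ENSGALG00000012135, 0.48 ± 0.07, adjusted p = 4.8e-05) and the amino acid transporter SLC38A2 (ENSGALG00000008497, 0.75 ± 0.09). A median of 0.24 went with a camera adjusted p = 0.0025 (0.36 with estimated r), with 14 higher and 5 lower over the list alone. Sterol genes rose in 12 of 20 cases and fell in 1, SREBF2 (0.73 ± 0.06, adjusted p = 2e-07) and MSMO1 (ENSGALG00000009560, 0.83 ± 0.12) among them. The median was 0.43, with 13 higher and 2 lower over the list alone, and a camera adjusted p = 2.7e-05 (0.45 with estimated r). ERK targets were higher in 9 of 19 cases and lower in 0, with EGR1 (1.07 ± 0.11) and DUSP6 (0.95 ± 0.14). Their median was 0.23 (camera adjusted p = 2.7e-05, 0.03 with estimated r), with 9 higher and 0 lower over the list alone. Cell cycle genes went down, 19 of 38 against 0, as with the mitotic proteins CENPF (ENSGALG00000009690, -1.20 ± 0.19) and TPX2 (ENSGALG00000006267, -0.96 ± 0.16) (adjusted p = 0.00026 or less). A median of -0.35 went with a camera adjusted p = 1.3e-08 (0.47 with estimated r), with 1 higher and 21 lower over the list alone.

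Genes of the citric acid cycle were lower after 24 h of DCA in 9 of 21 cases and higher in 1. The median was -0.17, with 2 higher and 12 lower over the list alone, and a camera adjusted p = 0.00031 (0.1 with estimated r). The drops were small, as for succinate dehydrogenase SDHA (ENSGALG00000013167, -0.28 ± 0.05, adjusted p = 0.0011). Nuclear genes of oxidative phosphorylation were lower in 16 of 56 cases and higher in 0 (median -0.12, camera adjusted p = 9.1e-05, 0.53 with estimated r, and 0.068 without the first control). Mitochondrially encoded genes were higher in 5 of 13 cases and lower in 0 (median 0.15, camera adjusted p = 0.00017, 0.44 with estimated r, and 0.11 with quantile scaling). They took 7.548% to 8.014% of the total with DCA and 6.827% to 7.324% in control. For the pyruvate dehydrogenase list, which holds the kinases that DCA inhibits, 2 of 12 fell and 0 rose (camera adjusted p = 0.8). The kinases PDK1 (ENSGALG00000013235) and PDK4 (ENSGALG00000009700) had log2 fold changes of 0.15 ± 0.12 (adjusted p = 0.43) and 0.27 ± 0.14 (adjusted p = 0.21). LDHA had a log2 fold change of 0.08 ± 0.12 (adjusted p = 0.69) and SLC2A1 of 0.08 ± 0.12 (adjusted p = 0.69). Among eye genes TYR (-1.08 ± 0.24, adjusted p = 0.0026) and PMEL (-0.59 ± 0.18) fell and ATOH7 (1.37 ± 0.29, adjusted p = 0.002) rose, while SIX6 had a log2 fold change of -0.20 ± 0.13 (adjusted p = 0.29). The PMEL call was lost without the first control (adjusted p = 0.097) or the third DCA replicate (adjusted p = 0.098). Large rises outside the lists were in the phosphatase PPEF1 (ENSGALG00000016522, 4.51 ± 0.33, adjusted p = 3.3e-08) and the gonadotropin subunit FSHB (ENSGALG00000012140, 3.62 ± 0.45), and large falls in AVD (ENSGALG00000025945, -3.20 ± 0.45), avidin, and SPP1 (ENSGALG00000010926, -3.01 ± 0.44, adjusted p = 6.6e-05), osteopontin. Of 14 blood markers 4 fell and 1 rose (median -0.20, camera adjusted p = 0.043, 0.53 with estimated r). The adjusted p was 0.13 without the second control, 0.15 without the third DCA replicate, and 0.051 to 0.053 without the second library of both compounds or the first or second DCA library at 48 h. A replicate block (0.051) and quantile and upper-quartile scaling (0.054 and 0.063) also ended that call. Of 29 further macrophage genes, chosen after the data were seen, 10 fell and 3 rose. In all, 3016 genes passed, 1594 higher and 1422 lower, 614 of them by at least 2-fold.

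With 48 h of DCA 5110 genes differed from control, 2541 higher and 2569 lower, 1208 of them by at least 2-fold. TXNRD1 reached 6186 ± 769 against 939 ± 56.3 normalized counts (2.71 ± 0.12, adjusted p = 3.7e-12), and SRXN1 (1.56 ± 0.11) and SQSTM1 (0.95 ± 0.07) were higher (adjusted p = 4.6e-09 or less), with 12 of 20 NRF2 genes up and 3 down. Their median was 0.37 (camera adjusted p = 0.00038, 0.16 with estimated r), with 13 higher and 3 lower over the list alone. Stress response genes rose in 22 of 30 cases and fell in 3, among them CEBPB (ENSGALG00000008014, 1.50 ± 0.16, adjusted p = 6.2e-07), the cystine transporter SLC7A11 (ENSGALG00000009758, 1.81 ± 0.24) and asparagine synthetase ASNS (ENSGALG00000009748, 0.87 ± 0.14). A median of 0.34 went with a camera adjusted p = 2.5e-05 (0.15 with estimated r), with 23 higher and 4 lower over the list alone. The p53 list had 10 of 17 higher and 1 lower, CDKN1A (1.38 ± 0.12, adjusted p = 6e-08) among them. The median was 0.33, with 11 higher and 1 lower over the list alone, and a camera adjusted p = 0.0043 (0.15 with estimated r). Sterol genes were higher in 17 of 20 cases and lower in 1, with SREBF2 (0.93 ± 0.06) and LSS (ENSGALG00000006198, 1.07 ± 0.10), lanosterol synthase. Their median was 0.66 (camera adjusted p = 1.7e-08, 0.28 with estimated r), with 18 higher and 1 lower over the list alone. Glycolysis genes rose in 10 of 21 cases and fell in 1, ALDOC (ENSGALG00000026077, 0.69 ± 0.06) and LDHA (0.50 ± 0.12) among them. A median of 0.24 went with a camera adjusted p = 0.0082 (0.28 with estimated r), with 10 higher and 1 lower over the list alone. Quantile scaling ended the calls of that list (camera adjusted p = 0.069) and of LDHA (0.06, adjusted p = 0.74). ERK targets had 8 of 19 higher and 0 lower, DUSP6 (1.01 ± 0.14) and DUSP4 (1.03 ± 0.12) included. The median was 0.16, with 8 higher and 0 lower over the list alone, and a camera adjusted p = 0.0016 (0.15 with estimated r). Of 38 cell cycle genes 8 fell and 0 rose (camera adjusted p = 0.18). Citric acid cycle genes fell in 8 and rose in 1 of 21 cases, nuclear genes of oxidative phosphorylation in 14 and 4 of 56 and mitochondrially encoded genes in 0 and 2 of 13 (camera adjusted p = 0.049, 0.016 and 0.049). These 3 calls ended with estimated r (0.37, 0.8 and 0.72) and without 1 of several single libraries (0.051 to 0.099, 0.069 to 0.078 and 0.051 to 0.17).

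Pigment genes were lower after 48 h of DCA alone in 16 of 26 cases and higher in 2. Their median was -0.67 (camera adjusted p = 0.00025, 0.29 with estimated r), with 2 higher and 16 lower over the list alone. PMEL (-1.40 ± 0.18, adjusted p = 4.5e-06), TYR (-1.55 ± 0.24, adjusted p = 3.7e-05), OCA2 (-0.69 ± 0.11) and OTX2 (-0.34 ± 0.08) fell, while MITF (0.66 ± 0.12, adjusted p = 0.00027) rose. The first DCA library at 48 h stood apart, with a chi-square of recovered reads per degree of freedom of 73.84 and 51.34 against the other 2, which gave 18.67 with each other, and pairs in other groups gave 15.51 to 30.24. It had the lowest PMEL and TYR of its group, 19828 and 5936 normalized counts against at least 30712 and 10984 in the others. Without it PMEL was at -1.14 (adjusted p = 1.8e-05) and TYR at -1.23 (adjusted p = 0.00027), CDH5 was at -0.58 (adjusted p = 0.0093), and 3978 genes passed. Of the retinal factors PAX6 (0.91 ± 0.16) rose, and SIX6 had a log2 fold change of -0.01 ± 0.13 (adjusted p = 0.95). Blood markers fell in 9 of 14 cases and rose in 1, among them the macrophage receptor CSF1R (-1.74 ± 0.18, adjusted p = 2.9e-07) and the leukocyte protein PTPRC (ENSGALG00000002192, -0.68 ± 0.16). A median of -0.67 went with a camera adjusted p = 0.0024 (0.37 with estimated r), with 1 higher and 10 lower over the list alone. Of 29 further macrophage genes, chosen after this was seen, 11 fell and 2 rose. Endothelial markers fell in 8 and rose in 0 of 10 cases, VWF (-1.21 ± 0.22) and CDH5 (-0.96 ± 0.22) included, CDH5 with an adjusted p = 0.072 when only the groups compared were fitted. The median was -0.88, with 0 higher and 9 lower over the list alone, and a camera adjusted p = 0.0011 (0.37 with estimated r). Among the largest changes, LYG2 (ENSGALG00000016761, from 194 ± 128 to 0 ± 0), AvBD1 (ENSGALG00000022815, from 113 ± 81.4 to 0 ± 0) and CATHL2 (ENSGALG00000019696, from 104 ± 96.6 to 0 ± 0) fell and PAPPA2 (ENSGALG00000040432, from 1.02 ± 1.77 to 153 ± 157) and the cyclin-dependent kinase inhibitor CDKN2B (ENSGALG00000026137, from 5.43 ± 5.15 to 318 ± 314) rose, in normalized counts with a wide spread between replicates. The matrix protease MMP9 (ENSGALG00000006992, 4.11 ± 0.25) rose too (adjusted p = 0.001 or less for these 6). The kinase PDK1 had a log2 fold change of 0.13 ± 0.12 (adjusted p = 0.47), and of 0.33 without the first DCA replicate (adjusted p = 0.019).

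Between 24 h and 48 h the DCA effect differed in 736 genes, 400 more positive and 336 more negative at 48 h, 255 of them by at least 2-fold. It was more positive for ACTA2 (1.50 ± 0.23, adjusted p = 0.0009) and for CYP24A1 (ENSGALG00000042279, 3.87 ± 0.74), which degrades vitamin D, and more negative for ATOH7 (-2.29 ± 0.41, adjusted p = 0.0029) and BMP4 (ENSGALG00000012429, -1.18 ± 0.23), a secreted growth factor. Of 28 matrix genes 5 were more positive and 1 more negative (camera adjusted p = 0.68), and of 17 BMP and TGF-beta genes 0 and 4 (camera adjusted p = 0.13). Endothelial markers lost in 3 of 10 cases. Their median was -0.71 (camera adjusted p = 0.00023, 0.61 with estimated r), with 0 positive and 4 negative over the list alone. Mesenchyme markers lost in 1 of 16 and gained in 0 (median -0.50, camera adjusted p = 0.002, 0.61 with estimated r). Of 38 cell cycle genes 0 passed, with a median of 0.35 (camera adjusted p = 0.00011, 0.84 with estimated r). At least 736 genes came from 11 of 100 splits of the libraries. The count depended on single libraries and on the method, being 385 when only the groups compared were fitted and 1233 with DESeq2 on recovered reads. It was 360 without the first DCA replicate at 24 h, 439 without the first control at 24 h, 474 without the second DCA replicate at 24 h, 434 without the first control at 48 h, 464 without the first DCA replicate at 48 h and 1058 without the second.

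Adding DCA to FGF2 for 24 h lowered cell cycle genes relative to FGF2 alone, 35 of 38 against 0 higher. A median of -1.08 went with a camera adjusted p = 6.1e-20 (0.15 with estimated r), with 0 higher and 36 lower over the list alone. The kinetochore and spindle proteins NDC80 (ENSGALG00000014801, -1.50 ± 0.14, adjusted p = 1e-07) and TPX2 (-1.63 ± 0.16) and the mitotic checkpoint kinase BUB1B (ENSGALG00000036892, -1.82 ± 0.17) fell, and CDKN1A (1.73 ± 0.12, adjusted p = 4.4e-09) rose from 1143 ± 239 to 3775 ± 610 normalized counts. Genes of the p53 list rose in 11 of 17 cases and fell in 0. The median was 0.53, with 11 higher and 0 lower over the list alone, and a camera adjusted p = 3.6e-05 (0.011 with estimated r). Matrix genes rose in 21 of 28 cases and fell in 1, LOX (2.11 ± 0.16, adjusted p = 8e-09), periostin POSTN (ENSGALG00000017046, 1.89 ± 0.18) and fibronectin FN1 (ENSGALG00000003578, 1.20 ± 0.15) among them, and mesenchyme markers moved with them, 9 of 16 higher and 2 lower. For the matrix genes the median was 0.58, with 21 higher and 2 lower over the list alone, and a camera adjusted p = 2.4e-07 (0.011 with estimated r). For the mesenchyme markers the median was 0.72, with 10 higher and 2 lower over the list alone, and a camera adjusted p = 0.0024 (0.29 with estimated r). Progenitor genes fell in 10 of 24 cases and rose in 0, with LHX2 (-0.92 ± 0.10, adjusted p = 4.1e-07) and SIX6 (-0.66 ± 0.13) lower. Their median was -0.39 (camera adjusted p = 0.00087, 0.13 with estimated r), with 0 higher and 10 lower over the list alone. SOX2 had a log2 fold change of -0.42 ± 0.26 (adjusted p = 0.22), and ATOH7 (1.32 ± 0.29, adjusted p = 0.0013) rose. TYR fell (-1.24 ± 0.24, adjusted p = 0.00033) and OTX2 (0.39 ± 0.08) rose. Of 14 blood markers 4 fell and 1 rose (median -0.37, camera adjusted p = 0.023, 0.44 with estimated r, and 0.069 and 0.086 without the third replicate of FGF2 or of both compounds).

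Stress genes rose with DCA in the FGF2 explants at 24 h. NRF2 genes were higher in 11 of 20 cases and lower in 2, TXNRD1 (2.38 ± 0.12, adjusted p = 5.2e-11) and SRXN1 (1.29 ± 0.11) among them, and stress response genes in 20 and 3 of 30, with SESN2 (ENSGALG00000037603, 1.94 ± 0.21), ATF4 (0.59 ± 0.07) and ASNS (0.89 ± 0.14). For the NRF2 genes the median was 0.36, with 12 higher and 2 lower over the list alone, and a camera adjusted p = 0.00011 (0.13 with estimated r). For the stress response genes the median was 0.46, with 20 higher and 3 lower over the list alone, and a camera adjusted p = 4e-05 (0.13 with estimated r). Nuclear genes of oxidative phosphorylation were lower in 19 of 56 cases and higher in 0, such as -0.25 ± 0.05 for the ATP synthase subunit ATP5B (ENSGALG00000038801, adjusted p = 0.00082). A median of -0.15 went with a camera adjusted p = 0.0013 (0.59 with estimated r), with 0 higher and 19 lower over the list alone. LDHA was higher (0.67 ± 0.12, adjusted p = 0.00017), the lactate exporter SLC16A3 (ENSGALG00000002728, 1.06 ± 0.13) was higher and SLC16A1 (ENSGALG00000001717, -1.19 ± 0.20) lower, the glycolysis list being 7 higher and 5 lower of 21 (camera adjusted p = 0.35). PPEF1 (5.02 ± 0.33) and the water channel AQP3 (ENSGALG00000002452, 4.24 ± 0.44) were among the largest rises, and the neuropeptide gene CALCA (ENSGALG00000006054, -3.93 ± 0.24) among the largest falls (adjusted p = 4.4e-07 or less). In all, 5373 genes passed, 2709 higher and 2664 lower, 1381 of them by at least 2-fold.

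At 48 h DCA with FGF2 differed from FGF2 alone in 7923 genes, 3817 higher and 4106 lower, 2507 of them by at least 2-fold. Retinal progenitor genes were lower in 16 of 24 cases and higher in 0. The median was -1.11, with 0 higher and 16 lower over the list alone, and a camera adjusted p = 2.1e-06 (0.045 with estimated r). SOX2 dropped from 2982 ± 204 to 781 ± 193 normalized counts (-1.96 ± 0.26, adjusted p = 1.4e-06), and RAX2 (-2.14 ± 0.16) and NOTCH1 (ENSGALG00000002375, -1.66 ± 0.11) fell (adjusted p = 5.4e-10 or less). SIX6 had a log2 fold change of -0.20 ± 0.13 (adjusted p = 0.2) and PAX6 of -0.10 ± 0.16 (adjusted p = 0.61). Neuronal genes fell in 20 of 25 cases and rose in 3. Their median was -1.78 (camera adjusted p = 0.00038, 0.18 with estimated r), with 3 higher and 20 lower over the list alone. ATOH7 dropped from 3156 ± 336 to 305 ± 78.6 (-3.39 ± 0.29, adjusted p = 3.6e-09), and FOXN4 (-3.05 ± 0.31), DLL1 (-2.23 ± 0.18) and the RNA-binding protein ELAVL4 (ENSGALG00000010533, -1.78 ± 0.13) fell as well (adjusted p = 4.9e-08 or less). Pigment genes went both ways, 6 higher and 8 lower of 26 (camera adjusted p = 0.81). MITF (0.65 ± 0.12, adjusted p = 0.00011) rose, and TYR (-1.25 ± 0.24, adjusted p = 0.00012) and the visual cycle genes RPE65 (ENSGALG00000011259, -1.99 ± 0.37) and RLBP1 (ENSGALG00000006676, -1.95 ± 0.28) fell. PMEL had a log2 fold change of -0.35 ± 0.18 (adjusted p = 0.11), with an adjusted p = 0.035 when only the groups compared were fitted and 0.046 without the third FGF2 replicate.

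All 38 cell cycle genes fell when DCA was added to FGF2 for 48 h, with E2F1 (-1.75 ± 0.12, adjusted p = 7.6e-11), CCND1 (-1.38 ± 0.11, adjusted p = 2e-09) and RRM1 (-1.36 ± 0.11) among them. A median of -1.32 went with a camera adjusted p = 5.3e-15 (0.19 with estimated r), with 0 higher and 38 lower over the list alone. CDKN1A rose (2.39 ± 0.12, adjusted p = 2.7e-12), as did 9 of 17 p53 genes, and 1 fell. The median was 0.38, with 9 higher and 1 lower over the list alone, and a camera adjusted p = 0.015 (0.18 with estimated r). CDKN2B (6.29 ± 0.91, adjusted p = 5.8e-06) was among the largest rises. Matrix genes rose in 24 of 28 cases and fell in 1: LOX went from 141 ± 14.5 to 1283 ± 155 normalized counts (3.18 ± 0.16, adjusted p = 1.7e-12), with VIM (ENSGALG00000008677, 1.43 ± 0.06), FN1 (2.29 ± 0.15) and TGFB2 (ENSGALG00000009612, 2.67 ± 0.17) (adjusted p = 6.8e-11 or less). Their median was 1.37 (camera adjusted p = 1.9e-09, 0.0059 with estimated r), with 24 higher and 1 lower over the list alone. Mesenchyme markers moved with them, 13 of 16 higher and 2 lower, including PRRX1 (ENSGALG00000003324, 2.89 ± 0.26) and LUM (ENSGALG00000011271, 2.77 ± 0.27). A median of 1.22 went with a camera adjusted p = 0.00046 (0.19 with estimated r), with 13 higher and 2 lower over the list alone. Endothelial markers rose in 4 and fell in 1 of 10 cases (camera adjusted p = 0.34), and of 16 further ones, chosen after the data were seen, 10 rose and 0 fell. Lysosomal genes rose in 16 of 27 cases and fell in 1 (median 0.25, camera adjusted p = 0.00038, 0.19 with estimated r), CTSK (ENSGALG00000028147, 3.14 ± 0.20), cathepsin K, among them.

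In the same comparison at 48 h, TXNRD1 (2.34 ± 0.12, adjusted p = 2e-12) and SQSTM1 (1.56 ± 0.07) rose, the NRF2 list having 12 of 20 higher and 4 lower. The median was 0.35, with 12 higher and 5 lower over the list alone, and a camera adjusted p = 0.0042 (0.19 with estimated r). Oxidative phosphorylation genes encoded in the nucleus fell in 30 of 56 cases, ATP5B (-0.62 ± 0.05, adjusted p = 3.9e-09) among them, and rose in 2. Citric acid cycle genes fell in 13 and rose in 1 of 21. For the oxidative phosphorylation genes the median was -0.19, with 2 higher and 30 lower over the list alone, and a camera adjusted p = 0.0016 (0.59 with estimated r). For the citric acid cycle genes the median was -0.21, with 1 higher and 13 lower over the list alone, and a camera adjusted p = 0.01 (0.19 with estimated r). LDHA rose (1.22 ± 0.12, adjusted p = 2.6e-08) while SLC2A1 (-0.69 ± 0.12, adjusted p = 6.9e-05) and ENO1 (-0.51 ± 0.08) fell, in a glycolysis list of 7 higher and 5 lower of 21 (camera adjusted p = 0.66). PDK1 fell (-0.76 ± 0.12, adjusted p = 2.6e-05) and PDK4 rose (0.74 ± 0.14, adjusted p = 0.0002). Of the ERK targets, DUSP6 (0.74 ± 0.14, adjusted p = 9.4e-05), EGR1 (1.56 ± 0.11) and FOSL2 (ENSGALG00000010036, 2.99 ± 0.20) rose and SPRY2 (-0.58 ± 0.13) and ETV5 (-0.69 ± 0.12) fell, and the list as a whole gave a camera adjusted p = 0.015 (0.19 with estimated r). The blood list did not move as one, with CSF1R (-1.69 ± 0.18) and PTPRC (-1.23 ± 0.16) lower and CD74 (ENSGALG00000004594, 1.21 ± 0.21) higher (camera adjusted p = 0.59).

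**Figure D3:**
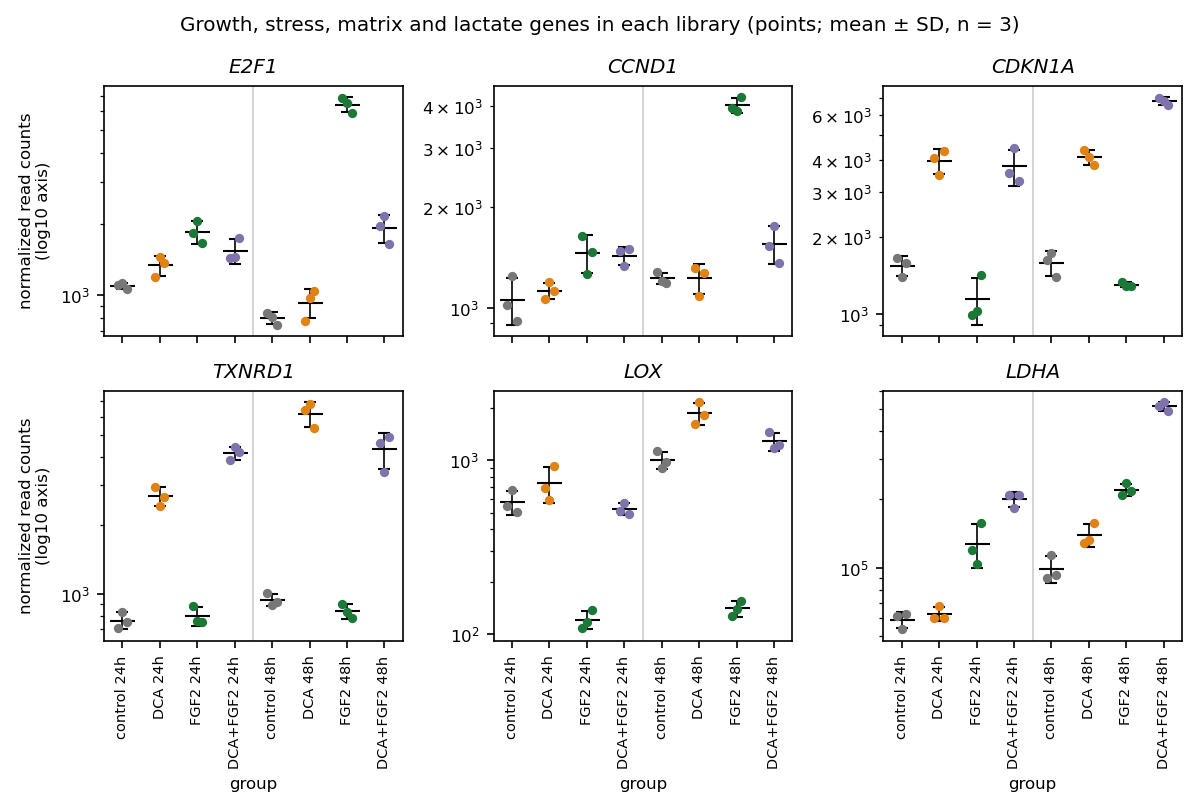
Normalized read counts (log10 axis) of E2F1, CCND1, CDKN1A, TXNRD1, LOX and LDHA in every library, with points for libraries and bars for group means ± SD, n = 3. CDKN1A averaged 1297 ± 27.5 with FGF2 and 6793 ± 224 with FGF2 and DCA at 48 h.

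The interaction asks whether the DCA effect was larger or smaller with FGF2 than without it. At 24 h 438 genes passed, 252 with a more positive and 186 with a more negative DCA effect in the presence of FGF2. Matrix genes had a positive interaction in 7 of 28 cases and a negative one in 0, LOX (1.76 ± 0.22, adjusted p = 0.00018), POSTN (1.96 ± 0.26), THBS1 (ENSGALG00000009626, 0.78 ± 0.12) and VIM (0.59 ± 0.09) among them. Their median was 0.42 (camera adjusted p = 1.5e-08, 0.0097 with estimated r), with 15 positive and 0 negative over the list alone. Of 16 mesenchyme markers, 6 of them also in the matrix list, 1 was positive and 0 negative. A median of 0.43 went with a camera adjusted p = 0.0013 (0.23 with estimated r), with 5 positive and 0 negative over the list alone. Cell cycle genes were negative in 5 of 38 cases and positive in 0, RRM1 (-0.76 ± 0.15) included. The median was -0.60, with 0 positive and 24 negative over the list alone, and a camera adjusted p = 5.4e-16 (0.23 with estimated r). The progenitor factor LHX2 (-0.74 ± 0.14) and the ERK phosphatase DUSP4 (-1.16 ± 0.17) were negative, and BMP2 (ENSGALG00000029301, 1.51 ± 0.17) was positive in a BMP list of 3 positive and 1 negative of 17 (camera adjusted p = 0.55). Progenitor genes passed in 2 negative and 0 positive cases of 24, and ERK genes in 4 and 1 of 19 (camera adjusted p = 0.0081 and 0.0096, 0.23 and 0.23 with estimated r). Of 13 mitochondrially encoded genes 1 was negative and 0 positive (median -0.22, camera adjusted p = 8.7e-08, 0.23 with estimated r). Their share of a library was 6.249% to 6.512% with both compounds and 6.703% to 6.993% with FGF2. For SIX6 and SOX2 the interaction was -0.46 ± 0.18 and -0.52 ± 0.36 (adjusted p = 0.18 or more). The count of 438, of which 177 were at least 2-fold, was 230 without the second and 572 without the third replicate of DCA with FGF2, and 238 without the first FGF2 replicate, and DESeq2 on recovered reads called 818. Of 100 splits of the libraries 15 gave at least 438 genes.

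At 48 h the interaction passed in 4517 genes, 2267 positive and 2250 negative, 1369 of them by at least 2-fold. It was negative in 37 of 38 cell cycle genes and positive in 0, E2F1 (-1.96 ± 0.16, adjusted p = 6.8e-08) and CCND1 (-1.38 ± 0.16) among them. Their median was -1.06 (camera adjusted p = 3e-17, 0.18 with estimated r), with 0 positive and 38 negative over the list alone. Progenitor genes were negative in 13 of 24 cases and positive in 2, with SOX2 (-2.75 ± 0.36, adjusted p = 8.9e-06), HES5 (-4.56 ± 0.48) and NOTCH1 (-1.35 ± 0.16), and neuronal genes in 9 and 1 of 25, with FOXN4 (-4.36 ± 0.44) and ATOH7 (-2.47 ± 0.41). For the progenitor genes camera gave an adjusted p = 7.1e-06 (0.064 with estimated r), with 2 positive and 14 negative over the list alone. For the neuronal genes the median was -1.52, with 1 positive and 11 negative over the list alone, and a camera adjusted p = 0.00018 (0.13 with estimated r). Sterol genes were negative in 18 of 20 cases and positive in 0, squalene epoxidase SQLE (-1.56 ± 0.18) included. A median of -0.94 went with a camera adjusted p = 3.4e-11 (0.14 with estimated r), with 0 positive and 19 negative over the list alone. Matrix genes were positive in 21 of 28 cases and negative in 1, SNAI1 (1.95 ± 0.17, adjusted p = 7.1e-08), VIM (1.06 ± 0.09) and FN1 (2.21 ± 0.21) among them. The median was 1.12, with 21 positive and 1 negative over the list alone, and a camera adjusted p = 2.1e-11 (0.0022 with estimated r). Beside them 14 of 16 mesenchyme markers were positive and 0 negative, and 8 and 0 of 10 endothelial markers. Medians were 1.38 and 1.07, with camera adjusted p = 2.3e-08 and 0.00049 (0.064 and 0.35 with estimated r). PMEL (1.06 ± 0.25), OTX2 (0.57 ± 0.11) and LDHA (0.72 ± 0.17) had positive and PAX6 (-1.01 ± 0.23) and PDK1 (-0.88 ± 0.18) negative values (adjusted p = 0.0029 or less), whereas SIX6 and DUSP6 gave -0.18 ± 0.18 and -0.27 ± 0.19 (adjusted p = 0.32 or more). Among 100 splits of the libraries, 7 gave at least 4517 genes.

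Explants given both compounds also differed from control, in 6337 genes at 24 h (3124 higher, 3213 lower) and 8170 at 48 h (4060 higher, 4110 lower), 1962 and 2911 of them by at least 2-fold. At 24 h ERK targets were higher in 14 of 19 cases and lower in 0, DUSP6 (2.20 ± 0.14, adjusted p = 7.4e-11) and SPRY2 (1.25 ± 0.13) among them. Their median was 0.82 (camera adjusted p = 3.9e-08, 0.0082 with estimated r), with 14 higher and 0 lower over the list alone. SIX6 (2.76 ± 0.13, adjusted p = 1.3e-12), SOX2 (2.53 ± 0.26) and ATOH7 (2.37 ± 0.29) were higher and TYR (-2.02 ± 0.24) and OTX2 (-0.77 ± 0.08) lower than in control (adjusted p = 1.2e-06 or less). LDHA rose from 58949 ± 4903 to 199731 ± 15271 normalized counts (1.76 ± 0.12, adjusted p = 2.7e-10). Blood markers were below control in 13 of 14 cases and endothelial markers in 6 of 10, with 0 and 0 above it (medians -1.22 and -0.78, camera adjusted p = 3.9e-06 and 0.01, 0.16 and 0.55 with estimated r). At 48 h pigment genes were below control in 20 of 26 cases and above it in 1, and TYR (-4.03 ± 0.24, adjusted p = 1.2e-11) and PMEL (-2.42 ± 0.18) fell. A median of -2.10 went with a camera adjusted p = 6e-09 (0.13 with estimated r), with 1 higher and 20 lower over the list alone. Progenitor genes were above control in 15 of 24 cases and below it in 2, with SIX6 (2.69 ± 0.13, adjusted p = 6.8e-13), SOX2 (3.60 ± 0.26) and PAX6 (1.84 ± 0.16). The median was 0.59, with 15 higher and 2 lower over the list alone, and a camera adjusted p = 0.0027 (0.16 with estimated r). Cell cycle genes were higher than control in 34 of 38 cases and lower in 0. Their median was 0.76 (camera adjusted p = 6.2e-08, 0.38 with estimated r), with 34 higher and 0 lower over the list alone. Mesenchyme, blood and endothelial markers were below control in 15 of 16, 13 of 14 and 10 of 10 cases, and 15, 13 and 10 over the list alone (medians -1.42, -1.69 and -1.89, camera adjusted p = 3e-06, 2.6e-06 and 5.9e-06, 0.13, 0.14 and 0.2 with estimated r). LDHA reached 513135 ± 23482 against 98741 ± 13316 in control (2.38 ± 0.12, adjusted p = 1.5e-12) and PDK1 fell (-0.81 ± 0.12, adjusted p = 1.2e-05).

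Against DCA alone, DCA with FGF2 differed in 3749 genes at 24 h (1952 higher, 1797 lower) and 5086 at 48 h (2607 higher, 2479 lower), 1051 and 1466 of them by at least 2-fold, which measures the FGF2 effect in the presence of DCA. At 24 h ERK targets rose in 10 of 19 cases and fell in 0. A median of 0.40 went with a camera adjusted p = 1.4e-05 (0.031 with estimated r), with 11 higher and 0 lower over the list alone. SIX6 (2.97 ± 0.13, adjusted p = 2.4e-12), SOX2 (2.43 ± 0.26), DUSP6 (1.24 ± 0.14) and LDHA (1.68 ± 0.12) rose and OTX2 (-0.75 ± 0.08) and SLC6A15 (-2.22 ± 0.17) fell in a pigment list of 11 lower and 0 higher of 26. For the pigment genes the median was -0.60, with 0 higher and 12 lower over the list alone, and a camera adjusted p = 0.00022 (0.21 with estimated r). Markers of other cells fell as well, 5 of 16 for mesenchyme, 12 of 14 for blood and 8 of 10 for endothelium, while 1, 0 and 0 rose. Medians were -0.45, -0.99 and -0.69, with camera adjusted p = 0.014, 1.1e-06 and 0.00038 (0.32, 0.17 and 0.26 with estimated r). The mesenchyme p was 0.1 without the third replicate of both compounds. At 48 h progenitor genes rose in 16 of 24 cases and fell in 1, cell cycle genes in 36 and 0 of 38, while pigment genes fell in 20 of 26 cases and rose in 1. For the progenitor genes the median was 0.91, with 16 higher and 1 lower over the list alone, and a camera adjusted p = 6.8e-08 (0.041 with estimated r). For the cell cycle genes the median was 0.89, with 37 higher and 0 lower over the list alone, and a camera adjusted p = 7.3e-17 (0.17 with estimated r). For the pigment genes the median was -1.22, with 1 higher and 22 lower over the list alone, and a camera adjusted p = 2.9e-10 (0.099 with estimated r). SIX6 (2.71 ± 0.13, adjusted p = 7.7e-12), SOX2 (2.81 ± 0.26) and ATOH7 (2.72 ± 0.29) were higher and TYR (-2.48 ± 0.24, adjusted p = 8.3e-08), PMEL (-1.02 ± 0.18), RPE65 (-3.96 ± 0.37) and MITF (-0.61 ± 0.12) lower (adjusted p = 0.00044 or less). At 48 h other-cell markers also fell, 13 of 16 for mesenchyme, 12 of 14 for blood and 9 of 10 for endothelium, while 0, 0 and 0 rose. Medians were -1.09, -1.03 and -1.07, with camera adjusted p = 7.6e-07, 1.5e-06 and 4.2e-05 (0.099, 0.12 and 0.19 with estimated r).

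**Figure D4:**
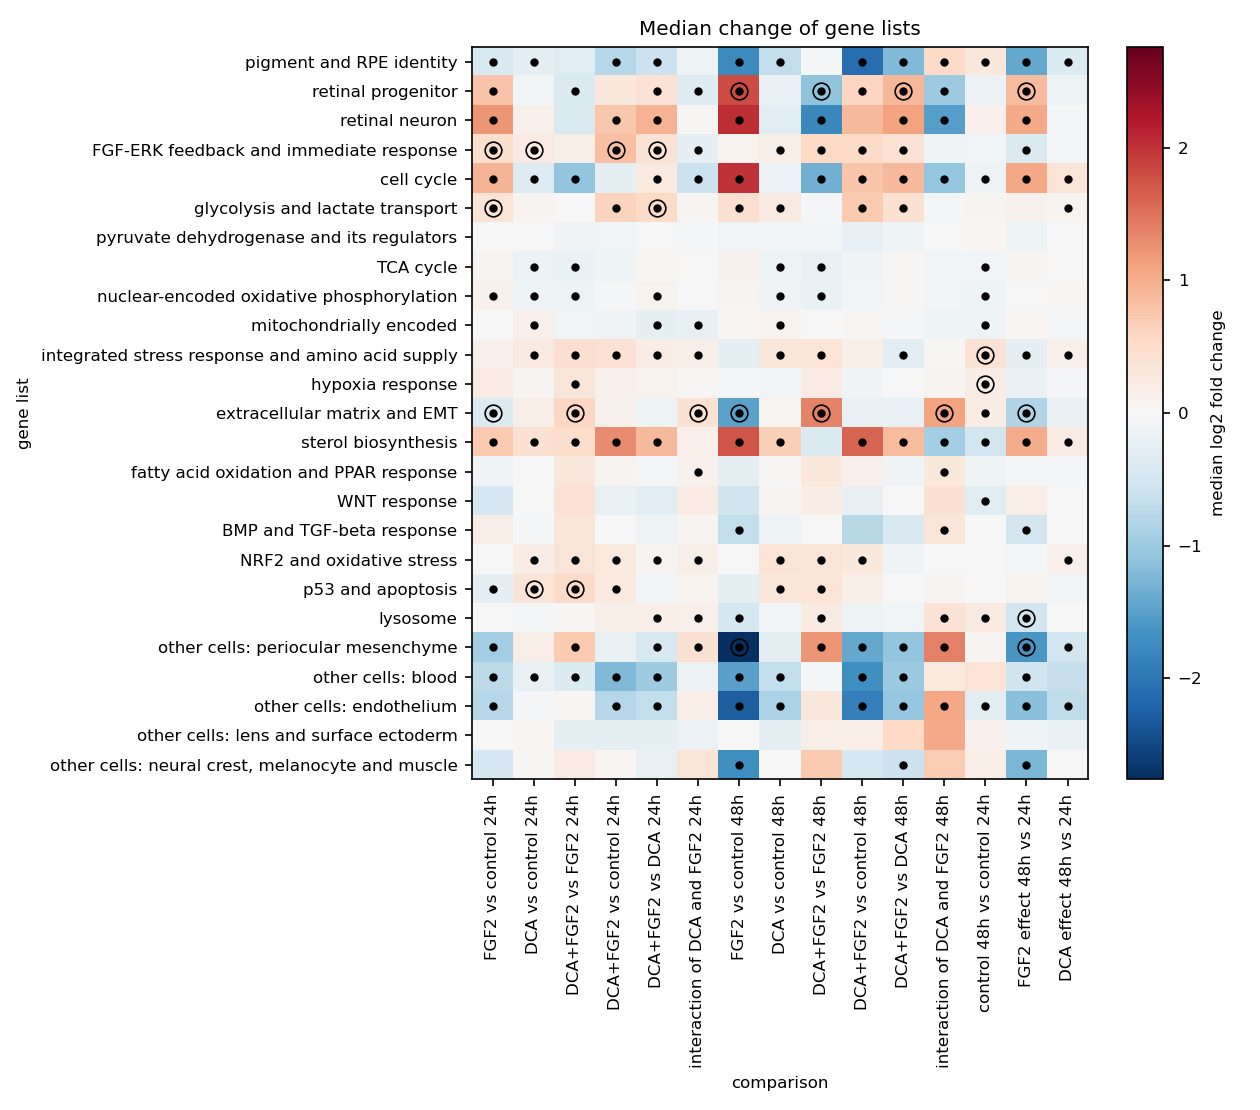
Median log2 fold change of each of the 25 gene lists (rows) in each of the 15 comparisons (columns), as a colour scale from lower (blue) to higher (red), with a dot where camera's adjusted p was under 0.05 and a ring where it was also under 0.05 with estimated r. Periocular mesenchyme in FGF2 against control at 48 h had a median of -2.76 and cell cycle in the same comparison 2.00.

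The DCA effect without FGF2 (DCA against control) was set beside that with FGF2 (both compounds against FGF2), comparisons that share no library. At 24 h the fold changes correlated across the 15001 genes at Pearson r = 0.483 and Spearman rho = 0.573, genes not being independent replicates. Of the genes called in both, 1146 were higher in both (287.9 for independent lists), 977 lower in both (252.5) and 36 went opposite ways. At 48 h r was 0.507 and rho 0.487, with 1639 higher in both (646.6), 1452 lower in both (703.2) and 474 opposite. The share of genes called with DCA alone that had the same sign with FGF2 present was 93.4% at 24 h and 79.1% at 48 h.

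Control explants themselves changed between 24 h and 48 h in culture, in 2549 genes, 1454 higher and 1095 lower at 48 h, 674 of them by at least 2-fold. Stress response and amino acid genes rose in 18 of 30 cases and fell in 0, the proline synthesis enzymes ALDH18A1 (ENSGALG00000034655, 1.27 ± 0.08, adjusted p = 1.8e-09) and PYCR1 (ENSGALG00000007300, 0.89 ± 0.10) and ASNS (0.91 ± 0.14) among them. The median was 0.40, with 20 higher and 0 lower over the list alone, and a camera adjusted p = 1.9e-11 (0.013 with estimated r). Hypoxia genes rose in 8 of 19 cases and fell in 0, NDRG1 (ENSGALG00000054783, 1.91 ± 0.14, adjusted p = 7.5e-09) and LDHA (0.74 ± 0.12) included. Their median was 0.20 (camera adjusted p = 4.8e-05, 0.013 with estimated r), with 10 higher and 0 lower over the list alone. Lysosomal genes were higher in 17 of 27 cases and lower in 0, with CTSS (ENSGALG00000000775, 1.05 ± 0.16), a gene also in the wider macrophage list, and sterol genes were lower in 16 of 20 cases and higher in 0, with SREBF2 (-0.43 ± 0.06) and LSS (-0.64 ± 0.10). Medians were 0.25 and -0.50, with camera adjusted p = 1.2e-07 and 1.9e-11 (0.12 and 0.17 with estimated r). Matrix genes rose in 11 of 28 cases and fell in 0, as with POSTN (2.01 ± 0.18) and COL3A1 (ENSGALG00000035584, 1.64 ± 0.20). A median of 0.21 went with a camera adjusted p = 0.0021 (0.13 with estimated r), with 11 higher and 1 lower over the list alone. Of 16 mesenchyme markers 5 rose and 2 fell (camera adjusted p = 0.5), and of 14 blood markers 7 and 4 (camera adjusted p = 0.12), CSF1R (2.15 ± 0.18, adjusted p = 5.2e-08) and C1QC (ENSGALG00000029669, 1.35 ± 0.19) among the higher. Of further genes chosen after the data were seen, 19 of 29 for macrophages rose and 1 fell (median 1.15), and 10 of 31 for mesenchyme rose and 1 fell (median 0.49). Of 10 endothelial markers 2 were lower and 0 higher. RBP4 (ENSGALG00000015374, 5.04 ± 0.23, adjusted p = 4.3e-12), the retinol-binding protein, and MITF (0.66 ± 0.12) and SIX6 (0.80 ± 0.13) were higher and ATOH7 (-2.29 ± 0.29, adjusted p = 1.4e-05) lower at 48 h.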

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

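For the 4 comparisons of effects, the test that permutes residuals was chosen only after the result of the split test was seen. The split test was written down before. In the 11 comparisons of 3 libraries with 3, the real grouping was the 1 of 10 splits with the most genes, and 10 splits cannot give a share under 0.1. The highest count of another split was 4 for FGF2 at 24 h, 3 for DCA at 24 h, and 2 each at 24 h for both compounds against FGF2, against control and against DCA. At 48 h it was 0 for FGF2, for DCA and for both against FGF2, 1 for both against control and 17 for both against DCA, and for control between times it was 3. For the effects compared, 15 of 100 splits gave as many genes as the 438 of the interaction at 24 h, 7 of 100 as many as the 4517 at 48 h, 8 of 100 as many as the 4524 of the FGF2 effect between times, and 11 of 100 as many as the 736 of the DCA effect between times. By its own rule this test did not exclude a random assignment of libraries to groups as the source of any of the 4 counts. It cannot decide that question, because every other split that reached a real count kept 1 or both pairs of groups together. The highest other counts, 6309, 8146, 6488 and 3349, came from splits that kept libraries of 1 or both pairs of groups together, which turns a difference of effects into a plain treatment effect. Splits that mixed both pairs, 79, 84, 82 and 83 of the 100, never reached the real count and gave at most 2, 1, 2 and 2 genes. With residuals of an additive fit permuted 100 times, the real count included, 1 of 100 was as large for each of the 4, and the highest other counts were 24, 1761, 1272 and 22.

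These values stand out because an effect differed between treatments or times. The 438 and 4517 genes are those whose DCA effect depended on FGF2 at 24 h and 48 h, and the 4524 and 736 genes are those whose FGF2 or DCA effect depended on time. For the interaction at 24 h the matrix list had a median of 0.42, with LOX at 1.76, POSTN at 1.96, THBS1 at 0.78, VIM at 0.59, BMP2 at 1.51, LHX2 at -0.74, DUSP4 at -1.16 and RRM1 at -0.76. At 48 h the matrix median was 1.12, with SNAI1 at 1.95, VIM at 1.06, FN1 at 2.21, PMEL at 1.06, OTX2 at 0.57 and LDHA at 0.72. On the negative side were SOX2 at -2.75, HES5 at -4.56, NOTCH1 at -1.35, FOXN4 at -4.36, ATOH7 at -2.47, E2F1 at -1.96, CCND1 at -1.38, SQLE at -1.56, PAX6 at -1.01 and PDK1 at -0.88. For the FGF2 effect between times the medians were 0.87 for progenitor, -0.83 for matrix, -0.52 for lysosomal and -1.60 for mesenchyme genes. The genes there were HES5 at 4.94, ATOH7 at 4.13, DLL1 at 2.85, SOX2 at 2.61, E2F1 at 2.26, CCND1 at 1.25, MITF at -0.94, OCA2 at -1.46, PMEL at -2.08 and TYR at -2.00. For the DCA effect between times they were ACTA2 at 1.50, CYP24A1 at 3.87, ATOH7 at -2.29 and BMP4 at -1.18.

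For the first pattern, markers of mesenchyme, blood and endothelium fell with FGF2 at 48 h. The test of further markers and the joint median of the lists were chosen only after that result was seen, while the scalings were planned. A smaller share of these cells in the FGF2 explants predicts that markers not looked at before fall too, and at least 74.2% of each of 3 such lists were called lower (23 of 31 for mesenchyme, 22 of 29 for macrophages, 14 of 16 for endothelium). The most abundant of each were CDH11, from 19950 normalized counts in control to 5071 with FGF2, STAB1, from 5522 to 2023, and ARAP3, from 5197 to 2390, while FBN1, next to CDH11, went from 15960 to 20870. Library scaling as the cause predicts a median near 0 under other scalings, and the median of the fixed lists stayed at -2.02 or lower. Lower expression in the same number of cells could give the same values, and cell numbers were not analysed here.

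For the second pattern, the interaction had 10.3 times as many genes at 48 h as at 24 h. Thinning, leaving out both deep libraries and the test of spread were chosen only after that result was seen. Both interactions held a deep FGF2 library of similar depth, so thinning all libraries to the same total cannot test depth as the cause. The ratio was then 11.2 (399 and 4465 genes). Without both deep libraries it was 9.92 (397 and 3937 genes), and with each time on its own 12 libraries 9.56 (440 and 4208 genes). A smaller spread between replicates at 48 h does not account for it, the median SD at 48 h being 1.01 times that at 24 h, a test whose prediction was written after its value was known. The ratio depended on the method, being 5.87 with DESeq2 on recovered reads (818 and 4804 genes), 7.73 with a 2-fold threshold (177 and 1369 genes) and 12.4 without a filter (347 and 4307 genes). The 24 h count itself was 230 to 572 with a library left out. No biological explanation was tested, so a response to the compounds that grows with time and a change in the mix of cells stay open.

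For the third pattern, macrophage genes such as CSF1R fell with DCA at 48 h, and all tests were chosen only after that result was seen. A smaller share of macrophages predicts that most macrophage genes not looked at before fall, and 37.9% were called lower (11 of 29, 95% interval 20.7% to 57.7%), against limits of 50% and 70% set in advance. Their median was -0.75 (SE 0.204), so as a group they fell, and a smaller share of macrophages stays open. Among the abundant ones STAB1 went from 5522 to 1967 and LCP1 from 4697 to 2104 normalized counts, while IRF8 was at 2385 and 2550. Dilution of all other cells predicts equal falls in mesenchyme and macrophage genes, and the medians differed by 0.18 (SE 0.3), too imprecise to tell from a moderate difference. A changed state of the macrophages could also lower only some of their genes.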

How the results depend on the processing

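A 2-fold threshold left 1483, 614, 1381, 1962, 1051 and 177 genes at 24 h (FGF2, DCA, both against FGF2, control and DCA, interaction), 3015, 1208, 2507, 2911, 1466 and 1369 at 48 h, and 674, 1492 and 255 for control, the FGF2 effect and the DCA effect between times, since it only removes genes. The interaction at 24 h (438) was 818 with DESeq2 and 230 to 572 with a library left out (230 without the second and 572 without the third replicate of both compounds, 238 without the first FGF2 replicate). The DCA effect between times (736) was 385 with only the groups compared, 1233 with DESeq2 and 360 to 1058 with a library left out (360 and 474 without the first and second DCA replicates at 24 h, 439 and 434 without the first control at 24 h and 48 h, 464 and 1058 without the first and second DCA replicates at 48 h). The DCA correlation (0.483 and 0.507) was 0.561 at 24 h with a pseudocount of 5, 0.358 and 0.394 without a filter, 0.59 and 0.555 with a mean of at least 50, and 0.467 to 0.506 at 48 h with a library left out, lowest without the first DCA replicate. Of 375 list tests 175 passed, 24 with an estimated correlation and 165 to 178 with a library left out. Only values near 0 changed sign. PMEL with FGF2 at 24 h (0.00) was -0.23 with quantile and -0.02 with upper-quartile scaling, and -0.12 to 0.12 with a library left out (lowest without the second and highest without the first FGF2 replicate), including -0.01 and -0.07 without the last 2 control replicates. SIX6 with DCA at 48 h (-0.01) was 0.01 with edgeR and DESeq2 and -0.16 to 0.16 with a library left out (lowest without DCA replicate 3, highest without DCA replicate 1), including 0.03 without control replicate 2. Replicate numbers did not pair libraries across groups (r of -0.092 to 0.097), and a replicate block gave 4381 genes for FGF2 at 24 h and 731 for the DCA effect between times. The alternatives that thinned depth or left out both deep FGF2 libraries were chosen after seeing the data. The cause of the other changes was not tested.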

Other observations

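LDHA, the enzyme that turns pyruvate into lactate, was highest where both compounds were given, at 513135 ± 23482 normalized counts at 48 h against 98741 ± 13316 in control, although DCA favours pyruvate oxidation. In the same explants the glucose transporter SLC2A1 and PDK1 were lower than with FGF2 alone. When DCA was added to FGF2, SOX2 and ATOH7 fell at 48 h while SIX6 did not pass, whereas at 24 h SIX6 fell, ATOH7 rose and SOX2 did not pass. In the pigment list 6 of 26 genes were higher and 8 lower at 48 h, with MITF higher and TYR lower.

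Cell cycle and matrix genes went opposite ways in the FGF2 and DCA comparisons, so it was asked after seeing this whether DCA reverses FGF2 responses in general. Of 4036 genes higher with FGF2 at 48 h, 2308 (57.2%) were lower when DCA was added, against 1105 expected for independent lists, and of 4151 lower genes 2062 (49.7%) were raised, against 1056. At 24 h 870 of 2322 (37.5%) were lowered and 827 of 2144 (38.6%) raised, against 412.4 and 387.2. These 2 comparisons share the FGF2 libraries, which alone gave a simulated r of -0.494 and covariance of -0.084, beside the observed r of -0.306 (covariance -0.227) at 24 h and -0.405 (covariance -0.486) at 48 h. With no library in common, r was -0.139 (covariance -0.13) for FGF2 at 24 h with DCA added at 48 h, and -0.202 (covariance -0.191) for the reverse. In the first, 979 of the 2322 higher genes were lowered and 639 raised, against 635.6 and 590.8 expected, and in the second 1350 of 4036 were lowered and 431 raised, against 716.7 and 728.9. The r of -0.139 lies between the limits of -0.1 and -0.2 set in advance, so it did not decide by those limits whether the shared libraries alone gave the opposition. In a test chosen after these values were seen, 95% intervals from residuals drawn with replacement ran from -0.222 to -0.014 and from -0.273 to -0.0471. Both lie under 0, which argues against shared libraries as the whole source. What else gave the opposition was not tested.

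CDKN2B, ANKRD1 and EMP1 were seen to rise when DCA was added to FGF2 at 48 h, and ANKRD1 is a known target of YAP, a regulator of tissue growth. After this was seen, 16 other YAP targets were tested, of which 11 rose and 0 fell (median 0.63, camera adjusted p = 0.00013, adjusted p = 0.03 with an estimated correlation). The most abundant, CCDC80, went from 9780 to 46550 normalized counts and F3 from 1144 to 4266, while AXL was at 5727 and 6507 and FJX1 at 5818 and 4928. A rise in YAP activity could account for this, and so could more mesenchymal or endothelial cells, since genes of both rose in the same comparison. Against control at 48 h, 14 of these 16 fell and 1 rose with FGF2 alone (median -0.56). With DCA alone 6 rose and 0 fell (median 0.26), and with both compounds 5 rose and 2 fell (median 0.01). The median with both thus lay near control, while single genes differed. CCDC80 was at 14850 normalized counts in control, 45940 with DCA alone and 46550 with both, and F3 at 6007, 11270 and 4266. Of these YAP targets the lists of mesenchyme genes hold only FOXF2.

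Photoreceptor genes such as RBP3 and GNAT2 were seen to rise in control explants between 24 h and 48 h. After this was seen, 20 other phototransduction and photoreceptor genes were tested, of which 7 rose and 2 fell (median 0.46, camera adjusted p = 0.0025, adjusted p = 0.049 with an estimated correlation). The most abundant, IMPG1, did not follow, at 27070 and 15430 normalized counts, while GNGT2 went from 4295 to 8038. Early photoreceptor genes in RPE or a few neural retina cells left in the explants could each give this pattern.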
